A study of Mus musculus with 2 samples.

How the data were processed

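Each library was made from total RNA of sorted thymic epithelial cells, extracted with TRIzol and prepared with an Illumina TruSeq kit, per the labels' protocols. The authors deposited 1 table per library with 1 FPKM value (fragments mapped to a gene, scaled by transcript length and by the total of mapped fragments) for each of 25791 gene symbols. TopHat2 2.0.8, Bowtie2 2.1.0, Cufflinks 2.1.1 and the genome build mm9 are named per the submitters' processing notes, without their roles. The gene annotation, the filters and the bias settings are not given in the sources used here. Neither is use of strand, so overlapping and antisense genes cannot be separated. No coordinates are given, because a genome of that build was not used here. No symbol was listed more than 1 time. Groups were taken from the titles of the libraries, because the treatment labels go against what is generally known of the transgene, and no library was regrouped from its values.

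Depth is not part of the deposited FPKM tables and was estimated from their low values, which fall on steps worth 1 fragment. Using transcript lengths of GENCODE annotation of a later genome build, less 210 bases, 1 fragment was worth 0.0502 FPKM over 1 kb in B6J and 0.0631 in humanCD3eTg. This corresponds to about 19900000 and 15900000 fragments. The step was searched between 0.04 and 0.09, a range narrowed after a wider search had settled on a smaller step in humanCD3eTg that did not match the ratio of the libraries. Of 486 and 376 low single-transcript genes used, 58.6% and 57.4% came out within 0.1 of a whole fragment, against 20% by chance for a step not chosen to fit, so the estimate is approximate and no count test was run. Without lengths, the most frequent ratio of values among 1806 low genes was 1.26, shared by 86 genes, where other windows of the same width beside it held a median of 5.5 and at most 19. The search range was narrowed with this ratio in view, so the match of the fitted steps to it is not an independent check. For 1 kb of length left after those 210 bases, 1 FPKM then rests on about 19.9 fragments in B6J (95% Poisson interval 12.2 to 30.9). In humanCD3eTg it rests on 15.9 (9.15 to 26.0). A transcript of 1 kb before this subtraction has fewer. These intervals cover counting error only. A value of 0 can be a failed estimate: Hmgcs1, a gene that dividing cells use and that was picked after its values were seen, is listed at 0 in both libraries. Such genes are said to be listed at 0 (FPKM of at most 0.001), and no fold or log2 ratio is printed for them. In all, 5790 genes were listed at 0 in both libraries and 2627 in 1.

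For each gene the log2 ratio of humanCD3eTg over B6J was computed on FPKM + 1. This pseudocount understates differences of low genes. Genes with a mean of at least 1 FPKM over the libraries were used, and a log2 ratio of at least 1 in size was counted as a 2-fold difference. Before the data were examined, 39 gene lists with 756 distinct genes were fixed (740 were found) for thymic epithelial subsets, signalling, antigen presentation, mesenchyme, other cell types, metabolism, stress and label checks. Also fixed were the comparison, the rule for named genes and the alternatives except those named below. The median ratio of each list with at least 5 used genes (37 lists) was set against 10000 random lists of the same size drawn from genes in the same of 20 expression bins, as a description of these libraries and not a test. Genes listed at 0 in 1 library entered list medians, counts of 2-fold differences and the ranking of named genes through the pseudocount.

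Genes were named by a fixed rule. It took the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 5 FPKM, leaving out small RNA genes and predicted genes. It further allowed up to 4 genes with the largest absolute ratio from each summarised list, and took 28 genes chosen in advance whatever their values, of which H2-Ea was not analysed here. Some genes that the rule names are not reported here. The computation was tested on simulated data for the 13493 genes used. It called 95 of 100 genes simulated with a 4-fold difference and 33 of 100 with a 2-fold difference, and 19 of 13293 unchanged genes. Of 100 unchanged lists of 18 genes 3 lay outside the random range, and of 100 lists shifted by 0.5 all 100 lay above it. The simulation used the same noise for all genes, taken from the spread of the real log2 ratios. It held no values of 0, no added noise for genes of few fragments and no spread between sorts. These counts therefore give no rate of false calls for the real libraries. The shift of 0.5 was added to each list median itself, so that result shows little.

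The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median centring, quantile normalization, rescaling without haemoglobin, mitochondrial and ribosomal protein genes, limits of 1.5-fold and 4-fold, removal of small RNA and predicted genes, and 50 expression bins. After the data were seen, removal of genes listed at 0 in 1 library and removal of marker genes of other cell types were added. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.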

Results

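RNA was sequenced from thymic epithelial cells of fetal mice at 15 days post coitum, sorted as negative for CD45 and PDGFRa and positive for EpCAM. There was 1 library titled B6J, from C57BL/6 mice, and 1 titled humanCD3eTg, from mice with a C57BL/6J x CBA/J background. The comparison asks how the thymic epithelium differs when developing thymocytes are present or absent. Mice with many copies of the human CD3E gene are generally known to lack T cells, yet the treatment label of humanCD3eTg states that thymocytes were present and that of B6J that they were absent. The groups are therefore named here by the titles of the libraries, and every direction below is that of the library titled humanCD3eTg relative to the library titled B6J. With 1 library per group there were no replicates, so no test was possible and no difference could be set against a spread between mice. Of 25791 genes, 13493 had a mean of at least 1 FPKM and were used. Differences of 2-fold are counted below on FPKM + 1, where genes of low level differ by less than in FPKM itself. The FPKM values total 682999 in B6J and 704134 in humanCD3eTg, with an estimated 19900000 and 15900000 fragments behind them.

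Transcripts of developing T cells were lower in humanCD3eTg. Cd3e, a chain of the T cell receptor complex, stood at 10.6 FPKM in B6J and 1.08 in humanCD3eTg (log2 ratio -2.48). Ptcra, the pre-T cell receptor alpha chain, stood at 8.60 and 1.02 FPKM (-2.25), and Rag1, which rearranges the receptor genes, at 8.35 and 0.127 FPKM (-3.05). Cd3g and Cd3d were listed at 45.5 and 18.7 FPKM in B6J and at 0 in humanCD3eTg. All 17 measured members of the thymocyte list were lower, 15 of them at least 2-fold with genes listed at 0 included, and the list median was -2.63. These include Il2ra, a receptor chain of early thymocytes (11.4 and 0.116 FPKM), and Lat, an adaptor of receptor signalling (12.7 and 0.184 FPKM). All 17 reached 1 FPKM in B6J, but only 7 did so in both libraries. With no filter the thymocyte median was -1.76 over 26 genes. Gzma, a protease of cytotoxic lymphocytes, stood at 56.6 FPKM in B6J and was listed at 0 in humanCD3eTg, and Il2rg, the common cytokine receptor chain, stood at 13.0 and 0.179 FPKM. Thus the library whose label states the presence of thymocytes held the lower level of thymocyte transcripts.

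Most lists of other blood and vessel cells were lower in the same library. Macrophage and dendritic cell genes had no stable direction, with a median of 0.33 and a mean of -0.13 over 7 genes. With no filter their median was -0.23 over 20 genes. Ptprc, which encodes the CD45 used for the sort, stood at 4.18 and 0.358 FPKM (-1.93). All 19 measured pan-haematopoietic genes were lower, 13 at least 2-fold (median -1.28), among them Coro1a, an actin regulator of leukocytes, at 25.2 and 2.22 FPKM, Ptprcap at 15.4 and 0.884 FPKM, Rac2 at 10.1 and 0.850 FPKM and Ikzf1 at 5.72 and 0.192 FPKM. Their median was -1.96 with a pseudocount of 0.1, -0.63 with 5 and -2.03 with a mean of at least 5 FPKM (8 genes). All 12 endothelial genes were lower, 10 at least 2-fold (median -1.48), including Pecam1 at 8.01 and 1.10 FPKM, Emcn at 8.90 and 1.36 FPKM, Ecscr at 7.60 and 0.974 FPKM and Plvap at 7.72 and 0.835 FPKM. The endothelial median was -2.44 with a pseudocount of 0.1, -0.65 with 5 and -1.16 with no filter (21 genes). All 12 endothelial genes reached 1 FPKM in B6J, but only 6 did so in both libraries. For the 19 pan-haematopoietic genes, all of which reached it in B6J, this number was 9. The 7 measured genes of B, NK and innate lymphoid cells had a median of -0.73, with 3 at least 2-fold lower, and of -0.29 with no filter (21 genes) or -0.31 with a pseudocount of 5. They include Tnfsf11, which encodes the cytokine RANKL (3.0 and 0.404 FPKM), Ltb, which encodes lymphotoxin beta (5.27 and 0.708 FPKM), Cd79a (2.89 and 1.35 FPKM) and Nkg7 (5.17 FPKM in B6J, listed at 0 in humanCD3eTg). Of 6 erythroid genes 5 were lower (median -0.71, or -0.27 over 13 genes with no filter): the adult haemoglobin genes Hba-a2 and Hbb-b1 stood at 950.6 and 567.3 FPKM and at 661.5 and 401.9 FPKM, and Alas2 at 4.19 and 1.68 FPKM. The embryonic Hbb-y stood higher, at 2.53 and 8.51 FPKM. Values of near-identical haemoglobin copies are uncertain.

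**Figure D1:**
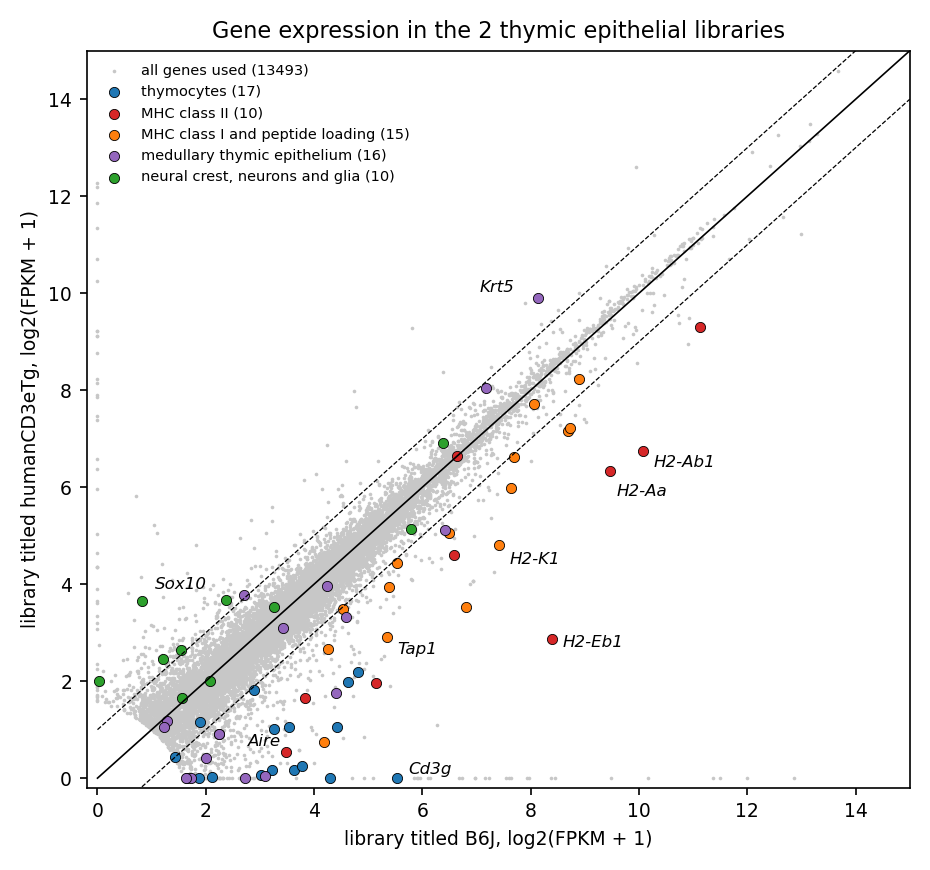
Expression of the 13493 genes used, as log2(FPKM + 1), in the library titled B6J (x axis) and the library titled humanCD3eTg (y axis), 1 point per gene, with 5 fixed gene lists in colour. The solid line marks equal values and the dashed lines a 2-fold difference. Most thymocyte and MHC genes lie below the lower dashed line.

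Antigen presentation genes were also lower in humanCD3eTg, from high levels in B6J. The class II genes H2-Ab1, H2-Aa and H2-Eb1, which encode chains that present peptides to CD4 T cells, stood at 1078 and 106.6 FPKM (-3.33), 707.2 and 79.7 FPKM (-3.13), and 336.9 and 6.33 FPKM (-5.53). Of 10 measured class II pathway genes 9 were at least 2-fold lower (median -2.57), including H2-DMb1, which helps load peptides (34.4 and 2.92 FPKM). In the class I list all 15 measured genes were lower, 13 at least 2-fold (median -1.51). The class I heavy chain genes H2-K1 and H2-D1 stood at 169.6 and 26.8 FPKM and at 111.3 and 10.5 FPKM, the peptide transporter gene Tap1 at 39.6 and 6.52 FPKM, and the immunoproteasome gene Psmb8 at 17.3 and 0.681 FPKM. Haematopoietic and endothelial markers moved with these genes (medians -1.28 and -1.48), and the strains differ at the MHC. H2-D1, H2-K1 and the gene model EG630612 (76.4 and 1.13 FPKM) may share reads with near-identical genes, so their values are uncertain.

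Genes of the interferon response were lower together with the MHC genes. Of 19 measured members 18 were lower, 11 at least 2-fold (median -1.11). Ifi47 and Irgm1, which encode interferon-induced GTPases, stood at 6.83 and 0.0429 FPKM and at 61.8 and 21.6 FPKM. Bst2, which encodes an antiviral membrane protein, stood at 25.7 and 3.24 FPKM, and Gbp3 at 7.22 and 1.27 FPKM. Ubd, a ubiquitin-like gene known to respond to interferon gamma and TNF, was listed at 17.7 FPKM in B6J and at 0 in humanCD3eTg. Among the chemokines, 8 of 18 genes were at least 2-fold lower and 3 at least 2-fold higher (median -0.51). The lower genes include Ccl21a, Ccl21b and Ccl21c, near-identical copies that may share reads, and Ccl19, listed at 0 in humanCD3eTg. The higher genes include Ccl17, listed at 0 in B6J. Cxcl9 and Cxcl11, known targets of interferon gamma, stood at 3.68 and 0.219 FPKM and at 4.52 and 0.169 FPKM, while Cxcl14 stood higher, at 2.52 and 13.6 FPKM (2.06). Thymocyte, haematopoietic and endothelial markers moved with both lists (medians -2.63, -1.28 and -1.48).

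Most medullary epithelial genes were lower, 13 of 16 measured, and 3 were higher. Aire, the regulator of tissue-restricted antigen expression, stood at 7.53 and 0.0366 FPKM (-3.04), Cd40, a TNF receptor family member, at 20.1 and 2.40 FPKM (-2.63), and Ccl21a, a chemokine gene with near-identical copies and therefore of uncertain level, at 84.3 and 33.5 FPKM (-1.31). Ccl19 was listed at 5.62 FPKM in B6J and at 0 in humanCD3eTg. Krt14 stood at 22.9 and 9.05 FPKM (-1.25), whereas Krt5, its usual keratin partner, stood at 280.2 and 955.5 FPKM (1.77) and Cldn3, a tight junction gene, at 5.49 and 12.7 FPKM (1.08). Of these 16 genes 9 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -1.28. This size depends on genes of low level: without genes listed at 0 in 1 library the median of the remaining 13 was -0.34, still below the central 95% of random lists. Tnfrsf11a, which encodes the receptor of RANKL, stood at 1.54 and 0.244 FPKM. In the list of NF-kB and TNF receptor signalling 17 of 20 genes were lower, 2 at least 2-fold (median -0.47), with Relb at 60.8 and 32.0 FPKM, Birc3 at 36.7 and 17.3 FPKM and Traf1 at 2.90 and 1.04 FPKM. The lymphoid and endothelial markers given above moved with these lists.

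Cortical epithelial genes were lower by small amounts. Of 17 measured members 15 were lower, none of them by 2-fold, and the median was -0.39, beside -2.63 for thymocyte, -1.28 for pan-haematopoietic and -1.48 for endothelial markers. Bmp4, also on this list, was the 1 member at least 2-fold higher on FPKM + 1. Prss16, the thymus-specific serine protease, stood at 1409 and 992.4 FPKM, Psmb11, the thymoproteasome subunit, at 65.6 and 51.8 FPKM, Ccl25, a chemokine that attracts progenitors, at 976.9 and 631.6 FPKM (-0.63), and Dll4, the Notch ligand that directs T cell fate, at 38.9 and 26 FPKM (-0.57). Cd274 stood at 87.5 and 48.2 FPKM and Ccrl1 at 18.9 and 11.7 FPKM. Il7, a cytokine for early thymocytes, stood at 113.0 and 110.6 FPKM, Cxcl12 at 288.9 and 220.8 FPKM and Kitl at 26.6 and 21.2 FPKM. Foxn1, the master transcription factor of thymic epithelium, stood at 91.1 and 43.7 FPKM (-1.04), while the epithelial surface marker Epcam stood at 173.5 and 231.4 FPKM (0.41). The wider list of thymic epithelial identity had a median of 0.05 over 18 genes, within the random range, with 2 genes at least 2-fold lower and 2 higher.

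**Figure D2:**
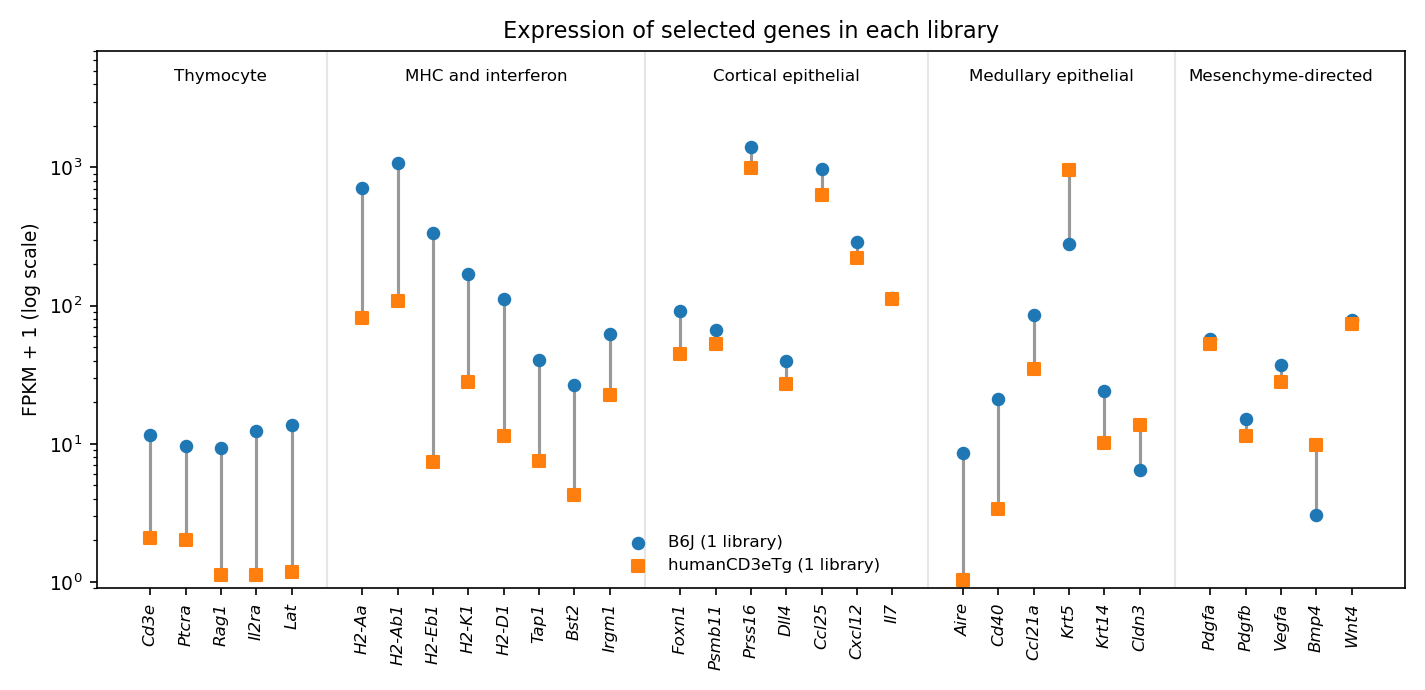
FPKM + 1 on a log scale for genes named by the fixed rule, in 5 groups, with 1 circle for the library titled B6J and 1 square for the library titled humanCD3eTg per gene, joined by a line. Thymocyte, MHC and interferon genes and Aire show wide gaps. Genes of the cortical epithelial group lie close together except Foxn1 (-1.04), which is on the identity list and not the cortical list. Krt5, Cldn3 and Bmp4 stand higher in humanCD3eTg.

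Genes for signals to mesenchyme, which the title of the study concerns, lay mostly within 2-fold on FPKM + 1. Pdgfa and Pdgfb, platelet-derived growth factors, stood at 56.7 and 52.0 FPKM and at 14.2 and 10.3 FPKM, Vegfa at 36.2 and 27.0 FPKM and Wnt4 at 77.2 and 72.4 FPKM. Bmp4 stood at 2.06 and 8.75 FPKM (1.67) and was the only 1 of 19 growth factor genes to differ by 2-fold on FPKM + 1. Neural crest genes were higher in the same library as Bmp4 (median 0.82). The growth factor list had a median of -0.23, above 422 of 10000 random lists and within their central 95%. In FPKM itself other growth factors were more than 2-fold lower. Fgf18 stood at 5.66 and 2.43 FPKM, Angpt1 at 2.78 and 0.993, Edn1 at 2.36 and 0.914, and Igf1 at 1.84 and 0.853 FPKM. No gene of the WNT list (median -0.23 over 14 genes) or of the FGF and BMP receptor list (0.07 over 17 genes) differed by 2-fold on FPKM + 1, and Fgfr2, the main epithelial FGF receptor, stood at 63.5 and 40.8 FPKM. In the Notch list (-0.01 over 16 genes) Heyl stood at 12.3 and 31.6 FPKM and Mfng at 2.18 and 0.464 FPKM.

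Mesenchymal genes showed no common direction within the sorted cells. Pdgfra, used as a negative marker in the sort, stood at 0.676 and 0.348 FPKM. The mesenchymal list had a median of -0.12 over 18 genes, the fibroblast matrix list -0.05 over 24 genes, and the list of epithelial-mesenchymal transition factors -0.02 over 16 genes with a mean of 0.00, all 3 within the random range. Individual members differed both ways. Vim, an intermediate filament gene, stood at 153.7 and 358.0 FPKM (1.21), Lox, a collagen cross-linking enzyme gene, at 1.85 and 10.4 FPKM (2.0), and Fbln2 at 3.75 and 11.1 FPKM (1.35). Tnc, which encodes tenascin C, stood at 254.8 and 92.6 FPKM (-1.45), Tgfbi at 11.3 and 2.06 FPKM (-2.01), Loxl2 at 12.4 and 5.16 FPKM (-1.12) and Tcf21 at 2.70 and 0.548 FPKM. Thy1, which thymocytes also express, stood at 23.8 and 2.97 FPKM. The basement membrane list had a median of -0.23 over 20 genes, none differing by 2-fold, with Itga6 at 21.8 and 12.4 FPKM. It lay at the edge of the random range and within it under 2 other settings.

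The genes with the highest ratios in humanCD3eTg included genes known from pigment cells and neural crest. Dct, a melanin synthesis enzyme gene, stood at 0.631 and 55.5 FPKM (5.11), Si, the silver locus of melanosomes, at 1.15 and 32.4 FPKM (3.96), and Sox10, a transcription factor of neural crest cells, at 0.776 and 11.6 FPKM (2.82). Mlana, a melanosome gene, and Ptgds, which encodes a prostaglandin D synthase, were listed at 0 in B6J and at 11.3 and 31.8 FPKM in humanCD3eTg. Fabp7, a fatty acid binding protein gene of glia, stood at 1.07 and 36.5 FPKM (4.18). Of 10 neural crest, neuron and glia genes 8 were higher, 5 at least 2-fold (median 0.82), with Erbb3 at 4.19 and 11.8 FPKM, Foxd3 at 0.0230 and 3.0 FPKM and Tubb3 at 1.32 and 4.48 FPKM. The size of this median depends on the filter, at 0.20 with none (18 genes) and 0.54 with a mean of at least 5 FPKM (5 genes), both above the random range. The other highest genes were Expi (listed at 0 in B6J, 13.9 FPKM in humanCD3eTg), Fxyd7 (3.34), Nr2e3 (3.26), Mcoln3 (3.23), Hopx (2.54 and 27.2 FPKM) and Krtdap, a keratinocyte differentiation gene (26.4 and 201.1 FPKM, 2.88).

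Epithelial junction genes were higher in 20 of 24 cases, 3 of them at least 2-fold (median 0.49). These were Pkp1, a desmosome gene, at 13.1 and 29.3 FPKM, Tjp3 at 1.61 and 4.24 FPKM, and Cldn3, given above. Cldn1 stood at 2.34 and 5.39 FPKM, with a log2 ratio of 0.94. In the keratinisation list 14 of 19 genes were higher, 3 at least 2-fold (median 0.36). They include Krt19 at 8.36 and 38.6 FPKM (2.08), Krt6a at 16.7 and 60.9 FPKM (1.81), Grhl3, a transcription factor of the epidermal barrier, at 2.5 and 9.23 FPKM (1.55), and Sprr1a at 115.5 and 199.4 FPKM. The keratinisation median was 0.68 with a mean of at least 5 FPKM (12 genes). With a pseudocount of 5 or no filter it was 0.23, still above the random range. Neural crest genes moved in the same direction as both lists. By contrast Sprr2a3, of the small proline-rich family with near-identical copies, stood at 29.4 and 0.812 FPKM. The remaining lowest genes were Lect1 (22.3 and 0.768 FPKM), Calcb, a calcitonin gene-related peptide gene (14.9 and 0.25 FPKM), and Il4i1 (11.7 FPKM in B6J, listed at 0 in humanCD3eTg).

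Cholesterol synthesis genes were lower together. All 19 measured members were lower (median -0.52), with Fdps at 79.2 and 49.0 FPKM and Lss at 13.1 and 7.16 FPKM. The lymphoid, haematopoietic and endothelial markers given above moved with this list and the S phase list. Genes of S phase had a median of -0.25 over 19 members, with Uhrf1 at 43.9 and 30.6 FPKM, while genes of G2 and mitosis had 0.08 over 20, with Cdk1 at 21.5 and 31.2 FPKM. Hypoxia and glycolysis genes had a median of -0.16 over 23, with Adm at 22.4 and 10.4 FPKM. The p53 target and apoptosis list (-0.05, mean 0.00), immediate early genes (0.03), heat shock and unfolded protein genes (-0.06), oxidative phosphorylation (0.04), cytosolic ribosome (0.16) and skeletal and smooth muscle (0.07) lay within the random range, the muscle list only without quantile normalization. So did the parathyroid and thyroid list (-0.21). Within these lists Cdkn1a stood at 77.4 and 131.4 FPKM, Socs3 at 165.0 and 56.7 FPKM, Atf3 at 167.4 and 249.4 FPKM, Hspb1 at 282.9 and 471.7 FPKM and Tagln at 7.65 and 32.3 FPKM. Macrophage and dendritic cell genes had a median of 0.33 and a mean of -0.13 over 7 members. Mpeg1 stood at 3.26 and 0.519 FPKM, Ctss at 3.73 and 0.877 FPKM and C1qb at 0.524 and 2.13 FPKM, and the median lay within the random range or turned negative under other settings.

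Sex-specific genes did not separate the libraries. Xist, expressed from the inactive X chromosome of females, stood at 17.5 and 17.2 FPKM, and Ddx3y, on the Y chromosome, at 7.14 and 8.22 FPKM, so both libraries held RNA of both sexes. The sex-specific list had a median of 0.18 over 5 genes. Nnt, part of which is missing in C57BL/6J mice, stood at 7.41 and 8.54 FPKM. H2-Ea, the other gene of the strain-dependent list, was not analysed here. The tissue-restricted antigen list had 4 measured members and was not summarised.

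**Figure D3:**
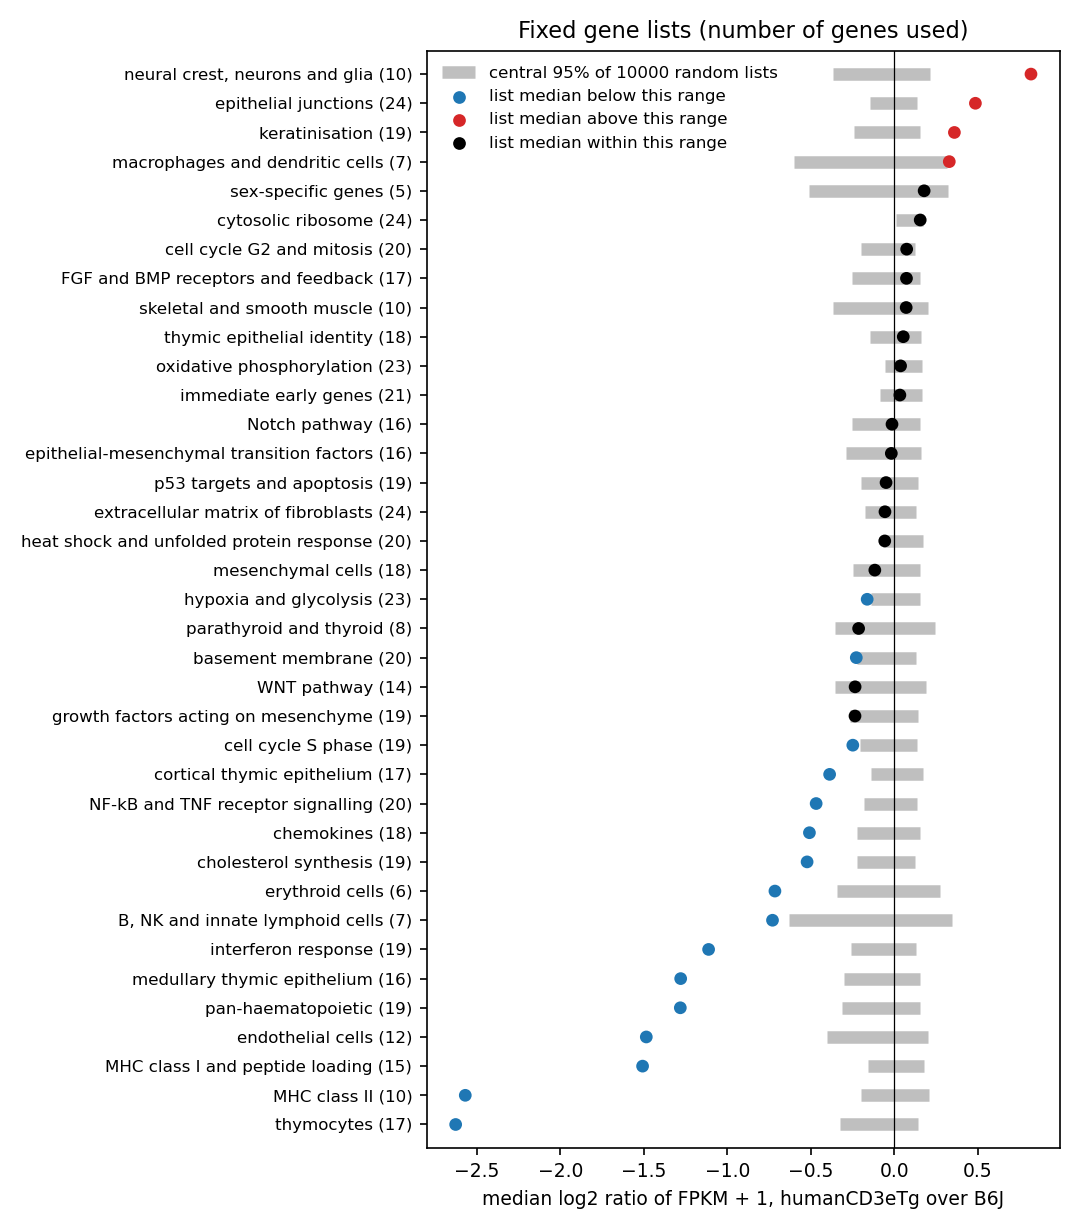
Median log2 ratio of FPKM + 1, humanCD3eTg over B6J, for the 37 gene lists with at least 5 genes used (points; number of genes in brackets), beside the central 95% of 10000 random lists matched on expression (grey bars). Of the 37 medians 16 lie below this range and 4 above it.

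Across all genes used, 603 were at least 2-fold lower and 284 at least 2-fold higher in humanCD3eTg, and 12606 (93.4%) lay within 2-fold. Of the lower genes 85 were listed at 0 in humanCD3eTg, and of the higher genes 42 were listed at 0 in B6J. Among all genes 7772 were listed at 0 in humanCD3eTg, the library with fewer estimated fragments, and 6435 in B6J. After quantile normalization of the libraries the split was 503 lower and 371 higher, so that lower genes made up 57.6% in place of 68.0%. Of the 37 list medians 16 lay below, 4 above and 17 within the central 95% of their random lists. If list members varied independently, 1.9 would lie outside by chance. Members of a list can vary together and some lists share genes, so 1.9 is no benchmark for these lists. The counts carry no error estimate, since a difference between 1 library and 1 library includes that between individual sorts, litters and strains.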

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

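The removal of genes listed at 0 in 1 library and of marker genes of other cell types were chosen only after the data were seen. Of the 20 lists outside the random range 18 stayed outside, on the same side, under every one of the 9 alternatives for list medians that gave a value, and of the 17 lists inside 16 stayed inside. The exceptions were as follows. The basement membrane median moved inside the range at -0.16 with a pseudocount of 5 and at -0.25 with haemoglobin, mitochondrial and ribosomal protein genes left out. The macrophage and dendritic cell median moved inside it at 0.39 with a pseudocount of 0.1, at 0.44 with quantile normalization and at 0.33 with 50 expression bins, and was reversed at -0.23 with no filter, where 20 genes entered in place of 7. The muscle median moved above it at 0.34 with quantile normalization. The cause of these shifts was not tested. Medians close to 0 inside the range changed sign under some settings for the Notch, epithelial-mesenchymal transition, fibroblast matrix, mesenchymal, immediate early, p53 and muscle lists. With a mean of at least 5 FPKM no value could be given for 6 lists left with too few genes (B, NK and innate lymphoid, WNT, endothelial, macrophage and dendritic, parathyroid and thyroid, sex-specific), nor for the ribosome and erythroid lists when their genes were left out.

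Counts of genes followed their limits by construction. Higher and lower genes numbered 473 and 903 with a pseudocount of 0.1, 106 and 223 with a pseudocount of 5, and 143 and 272 with a mean of at least 5 FPKM. They numbered 803 and 1471 at 1.5-fold, 66 and 171 at 4-fold, and 178 and 465 without small RNA and predicted genes. Without genes listed at 0 they were 242 and 518, and without marker genes of other cell types 273 and 556, against 284 and 603. Lower genes outnumbered higher genes under all 12 alternatives for the counts. Of the 181 named genes, 95 of which differed by at least 2-fold, none of these 95 reversed under the 4 alternatives run for them, and 115 of 724 values moved by more than 1.5 times, all under the other pseudocounts. The pseudocount also set the size of the thymocyte median, which was -4.49 with 0.1 and -1.36 with 5. For lists the measure is the ratio of the log2 medians, unlike that for named genes. By it the B, NK and innate lymphoid, S phase, endothelial, erythroid, keratinisation, medullary, neural crest and pan-haematopoietic medians also changed by more than 1.5 times. They did so under some setting while staying outside the range, for example 0.20 for neural crest with no filter. Such a ratio can come from a small shift: S phase moved from -0.25 to -0.16 with quantile normalization. The MHC class II median moved further, from -2.57 to -1.83 with a pseudocount of 5, without reaching that ratio. No scaling moved the median of all genes by more than 0.1 from 0. Keeping the highest of repeated symbols was not run, since no symbol was repeated. No paired analysis was possible because each group has 1 library and the libraries share no replicate numbers from the labels. Depth limits genes near 1 FPKM most, and a gene at 0 cannot be called absent. About 15.9 fragments in humanCD3eTg over 1 kb left after 210 bases leave a wide counting interval.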

Other observations

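All tests in this part were chosen only after the result was seen, except that of swapped treatment labels, and the genes named here outside the fixed rule were chosen after their values were seen. Beyond the genes at the top of the ranking, other pigment cell genes were higher in the library titled humanCD3eTg. Kit, the receptor of stem cell factor, stood at 4.01 and 13.3 FPKM in B6J and humanCD3eTg, Tyr, the tyrosinase gene, at 1.28 and 4.78 FPKM, and Pax3 at 0.0708 and 3.62 FPKM. Of 8 measured pigment genes outside the 12 highest 7 were higher, 6 at least 2-fold (median 1.43), while Tyrp1 and Oca2 were listed at 0 in both libraries. Several genes of stratified epithelium were also higher. Sbsn stood at 5.21 and 30.2 FPKM, Dmkn at 6.13 and 39.1 FPKM, Acpp at 13.0 and 69.6 FPKM and Zfp750, a regulator of epidermal differentiation, at 2.23 and 14.7 FPKM.

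Glutathione transferases, enzymes that conjugate glutathione to reactive compounds, were higher in 15 of 16 cases, 6 of them at least 2-fold (median 0.69). This group and the pigment group were put together because some of their genes were high, so their medians are no independent evidence. Gstm1 stood at 21.9 and 65.0 FPKM, Gsta2 at 1.83 and 8.77 FPKM and Gstt3 at 9.25 and 20.1 FPKM. These families hold similar copies, so single values are uncertain. Glo1, the glyoxalase gene, which is known to be duplicated in some inbred strains, stood at 67.7 and 143.7 FPKM, and Wdfy1 at 3.54 and 9.17 FPKM. Without Thy1 the mesenchymal median was -0.05, and without Ctss the macrophage and dendritic cell median was 0.35. The 18S ribosomal RNA gene Rn18s stood at 6097 and 9845 FPKM, and the gene model LOC236598, the largest value in both libraries, held 1.91% and 3.48% of the FPKM total.

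The labels go against the known effect of the transgene, and a candidate explanation is that the treatment labels were swapped: the thymocyte median of -2.63 lay below all 10000 random lists, so the library labelled as having thymocytes held less thymocyte RNA, and a value above the range would have spoken for the labels. Of the 17 genes of that list 1, Thy1, is on another list, and CD45 sorting would remove most such cells. A sort of B6J that was less pure for every other cell type alike is argued against, since the mesenchymal median lay 2.51 above the thymocyte median, with a spread among members of 1.23. Carry-over of some cell types only stays open, since the pan-haematopoietic (-1.28), endothelial (-1.48), erythroid (-0.71) and B, NK and innate lymphoid (-0.73) medians were also lower in humanCD3eTg, and the gate on PDGFRa removes mesenchymal cells. Swapped titles or files are argued against by the same median of -2.63 (spread 1.23), since the library titled humanCD3eTg would then be the one from mice with T cells, while H2-Ea was not analysed here and the log2 ratios of Nnt (0.18) and of Glo1 (1.08), picked after its value was seen, were not decisive.

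Lower MHC expression may reflect the lack of lymphoid signals to the epithelium, which was not tested and stays open. Sequence differences between the MHC haplotypes of the strains and the reference cannot act on reads of genes encoded outside the MHC. The 11 list members there had a median of -1.33, below all 10000 random lists, so the fall was not confined to genes within the MHC. Strain differences elsewhere in the genome were not tested. The median of the classical genes H2-K1, H2-D1, H2-Aa, H2-Ab1 and H2-Eb1 was -3.29, a difference of -1.96 from those 11 members. For both groups a strain effect cannot be told apart from a regulatory effect, because strain and title coincide. Macrophages carried over in B6J are argued against as the whole source of the fall. The median of 7 macrophage and dendritic cell genes lay 2.90 above that of the class II genes, with a spread of 1.47. With no filter the medians were -0.23 over 20 genes and -2.19 over 11. The 7 genes were divided, with 4 higher, 3 lower and a mean of -0.13, so a part from macrophages stays open. Dendritic cells cannot be judged, since their markers Itgax and Flt3 lay below the filter. Of those 7 genes 1, Ctss, is on another list, and the most abundant, Lyz2, stood at 11 and 8.80 FPKM.

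Pigment and neural crest genes in humanCD3eTg could come from a small number of such cells in that sort, although a gate on EpCAM would be expected to remove them. Without Sox10 the fixed list of neural crest, neuron and glia genes had a median of 0.54 over 9 genes, above 9994 of 10000 random lists. Of the 10 genes of the full list 8 reached 1 FPKM in B6J as well and 1 is on another list, and its most abundant genes were divided, with Stmn2 at 82.2 and 119 FPKM and Nefm at 54.6 and 34.0 FPKM. Whether skin keratinocytes were the source of the stratified epithelial genes could not be decided. Krt14 had a log2 ratio of -1.25 and reached 9.05 FPKM in humanCD3eTg beside 955.5 FPKM for Krt5, and Krt10 had a ratio of -0.10. These 2 were picked after their values were seen and were the only lower genes among 20 measured genes of stratified epithelium. The other 18 were higher, 15 at least 2-fold (median of all 20 1.66), in a group put together after the data were seen. Krt1 stood at 0.378 and 1.12 FPKM, and Krt14 also belongs to the medullary list, most of which was lower. A difference in coat colour genes between the strains, and a change in the epithelium itself, were not tested and stay open.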
